A study of Mus musculus with 14 samples.

How the data were processed

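The study measured RNA by sequencing in 14 libraries from adult mouse testis (C57BL/6), made along a purification of the chromatoid body, a perinuclear RNA and protein granule of round spermatids. Per the labels' protocols, dissociated tubule cells were crosslinked with formaldehyde, sonicated and centrifuged into a supernatant and a first pellet (pellet1), which was sonicated again, filtered and centrifuged into pellet2. Pellet2 was then immunoprecipitated (IP) with antibodies against MVH (the DEAD-box helicase encoded by Ddx4), against ACR (the acrosomal protease encoded by Acr) or with control IgG; the labels' sample types instead call the IPs made from lysate. The labels put the libraries in 9 groups: lysate (1), supernatant (1), pellet1 (1), pellet2 (1), MVH IP (3), ACR IP (3), IgG IP (1), sorted round spermatids (2, of which 1 from RNA selected above 500 bp) and round spermatids of mice heterozygous for MIWI (1). Libraries were primed with not-so-random hexamers and size-selected on a gel, per the labels' protocols. Whether the counting used strand is not given in the sources used here, so a gene and an overlapping or antisense gene could not be told apart. Values of the IgG and ACR IP libraries were not analysed here.

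Per the submitters' processing notes, the tools were TopHat and Cuffdiff and the genome build was mm9; their versions, read filters and read counts are not given in the sources used here. The deposited values came in FPKM per the file headers, in a joint Cuffdiff table of 5 conditions (lysate, supernatant, pellet1, pellet2, MVH IP) and in separate tables for genes, transposable elements, piRNA clusters and other RNAs. The joint table, with 10 pairs of conditions, lists 27024 features, of which 21905 carry a gene symbol, 4922 are assembled transcripts without one and 197 are piRNA clusters. The deposited notes do not say how the conditions were scaled. Each condition has 1 deposited value per feature, listed by the labels for all 3 MVH IP libraries and both round spermatid libraries, so values of single libraries could not be separated. MVH IP differed between pairs of conditions for 12 features of the joint table, and the highest of its values was then used. The separate gene tables and the MVH IP and round spermatid element tables were scaled by the authors apart from each other and list features from 5 FPKM upward (the lowest gene value was 5.00 FPKM), so a missing feature is below that floor or unlisted. The round spermatid piRNA table has no such floor and starts at 0. The deposited FPKM unit of the other RNA tables, which have no header, was inferred from the values. The q-values and p-values in the authors' deposited table come from Cuffdiff, per the file headers; the authors' calls were counted as deposited, at q under 0.05. The lysate element table names its value FPKM per the file headers, but 27.6% of its values were whole numbers (tolerance 0), its lowest value was 21.0 and its values had a rank correlation of -0.01 with element length, against -0.31 for MVH IP; those deposited values were therefore kept as a score with no fixed unit and set against no other table. A small RNA column paired with the MVH IP values, 1 in number, belongs to another kind of library and was not used here. Coordinates are mm9, counted from 1.

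The design, the gene lists and the rule for named genes were fixed before the data were examined. The design assumed 1 column per library and a limma test; pooled values allow no test, so its stated fallback was used. For each comparison the log2 ratio of (FPKM + 1) was taken for genes with a symbol and a mean of at least 1 FPKM, and a gene was called higher or lower at 2-fold or more. Fold changes are on that log2(FPKM + 1) scale, which understates the change of low genes. There is no standard deviation, n or p-value of these comparisons, and no difference has a replicate check. A gene listed at exactly 0 can be a failed estimate and is given no fold. Comparisons across the separate tables use genes listed in both. Where the median log2 ratio of all genes moved by over 0.1, changes are also given relative to it, called centred.

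There were 22 gene lists (chromatoid body proteins, piRNA pathway, nonsense-mediated decay, haploid nuclear condensation, acrosome, flagellum, haploid retrogenes, X and Y multicopy genes, meiotic spermatocytes, spermatogonia, Sertoli, Leydig, and peritubular, vascular and blood cells, ribosomal proteins, the nuclear and the mitochondrial genes of the respiratory chain, histones, proteasome, nuclear-retained noncoding RNAs, small nucleolar RNA hosts, small nucleolar and nuclear RNAs, and microRNAs). The median log2 ratio of each list with at least 5 measured members was set against 10000 random lists of the same size matched on mean level in 20 bins, and its percentile is given as a description of these values. The mitochondrially encoded list had no measured member (1 list of 22). Named genes were, by rule, the 10 largest increases and decreases at a mean of at least 5 FPKM, up to 4 members of each list with the highest mean, every chromatoid body list member, Ddx4 and Acr, and for elements, clusters and other RNAs the 5 highest and 5 most changed. Since genes listed at 0 filled most of the largest changes in the joint table, the 10 largest among genes above 0 in both conditions, the largest of the authors' calls, and a short set of further genes (Aard, Cldn11, Rhox8, Snord58b, Ip6k1, Braf and Spata6 among them) were added after values were seen, as was the comparison of MVH IP with pellet2, from which it was made per the protocol text. Some results that the rule selects are not reported here.

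The files hold no counts or totals, so the depth of each library is unknown and no interval is given. FPKM is poorly defined for genes shorter than the sequenced fragments, so the very high values of small nucleolar RNA genes are not abundances on the scale of messenger RNAs. Several are listed with the span of a longer merged gene (Snord58b at 18:75160131-75163035), and reads shared with the host gene, or among near-identical copies such as the X and Y multicopy families, cannot be told apart.

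Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The calling and list steps were tested on simulated data for MVH IP against lysate over 12824 genes with noise of 0.3 log2: of 200 genes changed 4-fold, 100% were called in each direction, 0.0158% of unchanged genes were called, 6.5% of 200 unchanged lists of 30 genes lay outside the central 95%, and a list raised by 0.5 lay at percentile 100. The simulation had no shift of all genes and changed only genes at 5 FPKM or more in lysate. The real log2 ratios had a median of 0.92 and quartiles of 0.10 and 1.68. These rates therefore check the steps and do not measure errors in the real calls. Alternatives tried were a pseudocount of 0.1, no filter, a mean of at least 5 FPKM, centring and a 4-fold threshold, and, added after seeing the data, all features, genes above 0 in both conditions, other reference conditions and the other deposited table of the same group.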

Results

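RNA was measured in adult mouse testis along the purification of the chromatoid body, a perinuclear granule of round spermatids rich in the helicase MVH and in the piRNA machinery. The 14 libraries fall into 9 groups, of which values of 7 are described. The joint table holds 5 conditions with 12803 genes at 1 FPKM or more in lysate, 12675 in supernatant, 12613 in pellet1, 12744 in pellet2 and 13590 in MVH IP. Above 0 FPKM, MVH IP had the fewest genes, 15959, against 17989 in lysate, 18437 in supernatant, 16350 in pellet1 and 16140 in pellet2. The median gene was at 3.96 FPKM in MVH IP and 1.83 in lysate. In each condition the 10 highest features, all small nucleolar or Cajal body RNA genes, held 66.4% to 77.5% of the summed FPKM. Sequencing depth is unknown and there are no replicates in the values, so every difference is given as a size without an error.

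The comparison of MVH IP with lysate asks which RNAs the purified chromatoid body holds relative to the testis it came from. No control IP was used here, so what the antibody brought down cannot be told from nonspecific carry-over. Among the large differences, Adam23, a membrane disintegrin (1:63492478-63643089), was at 577 FPKM in MVH IP and 20.6 in lysate, 26.8-fold higher. Adam23 was also above lysate in pellet1, at 148 FPKM, and in pellet2, at 256, so its difference is not particular to the IP. Commd4 was at 77.3 FPKM in MVH IP and 1.47 in lysate. Neat1, the long noncoding RNA of nuclear paraspeckles (19:5842302-5845478), was at 11.5 and 76.7 FPKM, a log2 ratio of -2.64, and Malat1, a nuclear speckle RNA, at 114 and 626, or -2.44. Ddx4 itself, the transcript of the immunoprecipitated protein (13:113388541-113442518), was at 280.3 and 282 FPKM, and Acr at 275 and 156. The separate gene tables, scaled apart, list Ddx4 at 249.9 and 121 FPKM and Acr at 209 and 62.1, so these ratios depend on the table.

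The genes of the chromatoid body and of the piRNA pathway stood low in MVH IP relative to all genes, whose median log2 ratio was 0.92. Of 32 genes encoding chromatoid body proteins 3 were higher and 3 lower by 2-fold or more (0 and 13 after centring), with a median of -0.88 relative to all genes at percentile 0.11 of matched lists. Piwil1, the gene of the piRNA-binding protein MIWI, was at 36.8 and 106 FPKM, Tdrd6 at 96.1 and 201, and Ddx25, a spermatid RNA helicase, at 60.5 and 174. Tnrc6a, a partner of Argonaute proteins, was higher at 11.9 and 3.64 FPKM. Of 19 piRNA pathway genes 5 were higher and 2 lower (0 and 6 centred), at percentile 1.46. Among 18 genes of nonsense-mediated decay 10 were higher and 1 lower (2 and 4 centred), at percentile 74.9, among them Upf2 at 159 and 34.5 FPKM.

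Spermatid genes were split. Of 41 flagellum genes 11 were higher and 2 lower (1 and 17 centred), at percentile 0.21, while 15 condensation genes lay at 36.7, 22 acrosome genes at 39.8 and 31 retrogenes at 23.8. The packaging protein transcripts were high in both samples, with Tnp1 at 15140.4 and 15259 FPKM and Prm1 at 8200.5 and 13795. The separate gene tables, scaled apart, list Tnp1 at 14304.4 and 7609 FPKM and Prm1 at 4442 and 5046.5, so their ratios depend on the table. X and Y multicopy genes, with 8 higher and 1 lower of 10 (4 and 1 centred), lay at percentile 95.4; Sly was at 66.3 and 3.55 FPKM, although reads of its near-identical copies cannot be told apart. Of 23 Sertoli cell genes 15 were higher and 4 lower (10 and 4 centred), at percentile 99.7 but 97.0 with a pseudocount of 0.1, with Ctsl (13:64464522-64471614), a lysosomal protease, at 127 and 14.6 FPKM. Of 14 Leydig cell genes 4 were higher and 2 lower (1 and 9 centred), at percentile 0.02, with Cyp17a1 at 84.5 and 139.5. Among the housekeeping lists, 75 ribosomal protein genes had 15 higher and 11 lower (4 and 33 centred) at percentile 0, 58 histone genes lay at 1.37 and 35 proteasome genes at 1.9, or 3.13 without the filter on low values and 3.06 at a mean of 5 FPKM. The 88 respiratory chain genes lay at 4.25 (31 higher and 5 lower, 9 and 16 centred), with Cox8c, a testis subunit, at 1809 and 260.3 FPKM. Percentiles of the 31 meiotic, 15 spermatogonial, 25 peritubular, vascular and blood, and 10 small nucleolar RNA host genes were 15.9, 76.8, 29.6 and 72.4. Of 10 nuclear-retained noncoding RNA genes 0 were higher and 6 lower, and of 99 small nucleolar and nuclear RNA genes 15 were higher and 51 lower, both at percentile 0. The 53 microRNA genes split into 19 higher and 30 lower, at percentile 0 with genes listed at 0 kept and at 91.2 without them.

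Of 13855 genes tested, 6554 were at least 2-fold higher and 1043 lower, of which 249 and 404 were listed at 0 in the other sample. After centring, which evens out the directions by construction, the split was 2587 and 2852, and 11 of 21 lists lay outside the central 95%. The largest changes by size were microRNA genes listed at 0 in lysate (Mir1940 at 1605 FPKM) and small nucleolar RNA genes listed at 0 in MVH IP (Snord11 at 13157 in lysate), and such zeros can be failed estimates. The authors' deposited table calls 735 genes higher and 12 lower. In the authors' deposited table Adam23 had q = 9.69e-12, Upf2 0.0134, Neat1 0.0294, Malat1 0.143, Piwil1 0.197 and Ddx4 0.999.

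**Figure D1:**
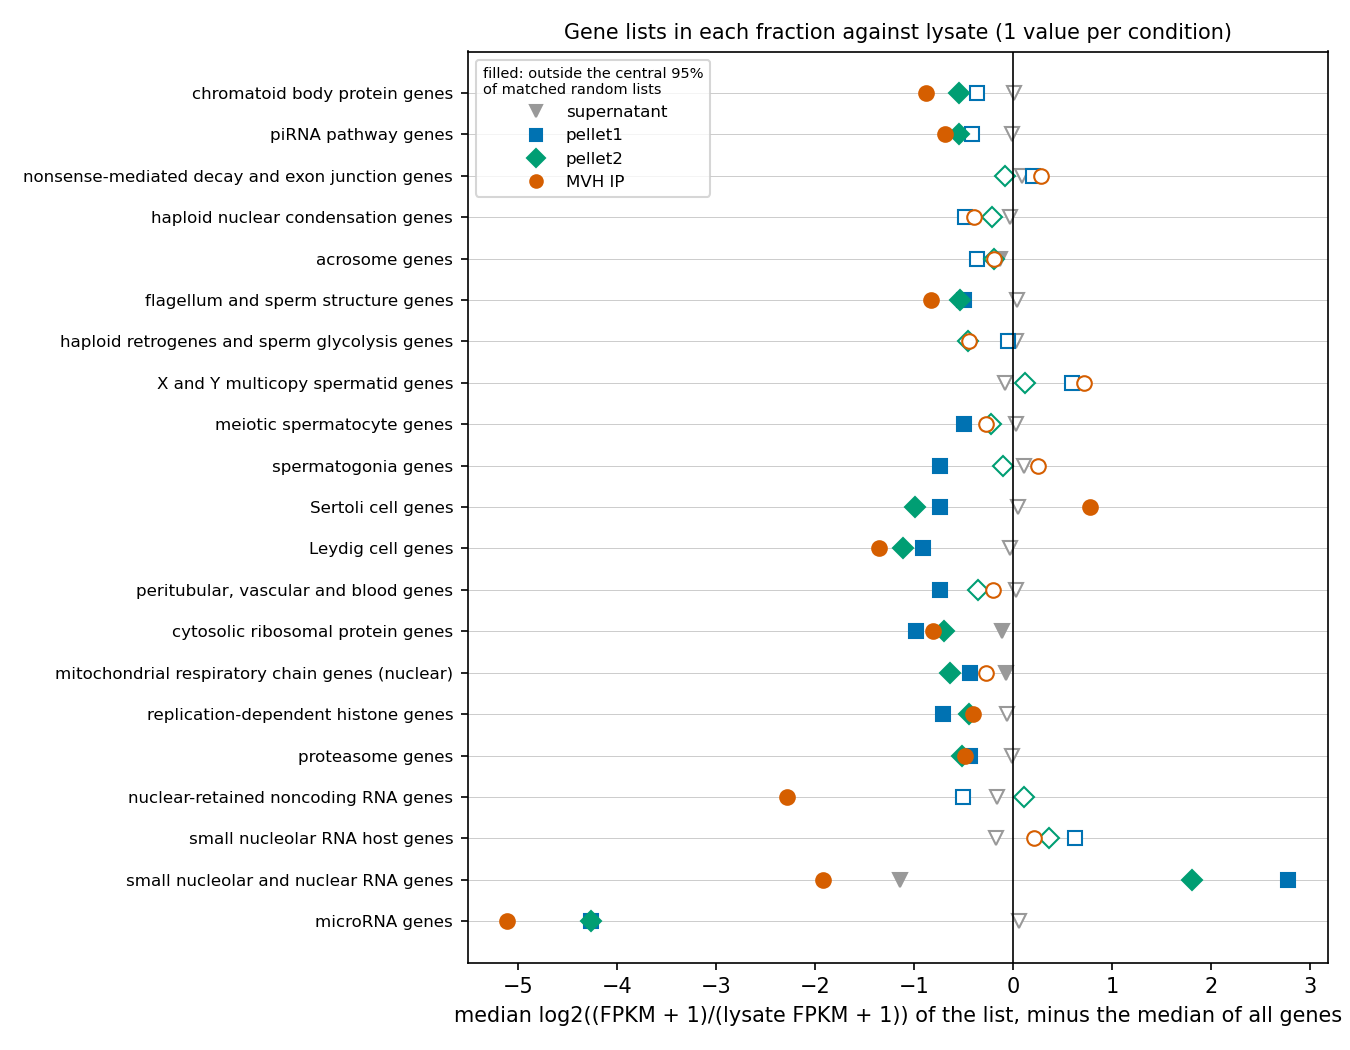
Median log2 ratio of each gene list against lysate minus the median of all genes, for supernatant, pellet1, pellet2 and MVH IP; filled points lie outside the central 95% of 10000 matched random lists. The small nucleolar and nuclear RNA list lies at 2.78 in pellet1 and at -1.92 in MVH IP.

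The purification steps were compared with lysate to follow RNAs from the first spin to the second pellet. Supernatant stayed close to lysate in most lists, while many small nucleolar RNA genes, whose products guide modification of ribosomal and spliceosomal RNA, and microRNA genes differed. Snord58b was at 104622 FPKM in supernatant and 314040.0 in lysate, and then at 6024400.0 in pellet1 and 3415580.0 in pellet2. Gas5, a host gene of several such RNAs, was at 162 FPKM in pellet1, 112 in pellet2 and 21.7 in lysate.

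In supernatant 60 of 99 small nucleolar and nuclear RNA genes were at least 2-fold lower and 1 higher (percentile 0), among them Snord96a at 496 and 4531 FPKM. Chromatoid body genes had a median 0.01 from that of all genes, at percentile 49.3, and Ddx4 was at 298 FPKM against 282. Acrosome, ribosomal and respiratory chain genes lay at percentiles 0.29, 0 and 0.21, but by small shifts of -0.13, -0.11 and -0.07. Of 63 microRNA genes 29 were higher and 21 lower, at percentile 96.8 but 1.77 when genes listed at 0 were left out. In all 96 genes were higher and 186 lower of 12777, and the authors' deposited table calls 0 genes higher and Snord58b lower (q = 0.0361).

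In pellet1 96 of 108 small nucleolar and nuclear RNA genes were higher and 2 lower, and in pellet2 84 of 107 were higher and 11 lower, at percentile 100 in both. Ribosomal protein genes were lower, with 32 of 75 in pellet1 and 22 of 75 in pellet2 and 3 higher in each, at percentile 0, as Rps28 at 119 and 92.6 FPKM against 341. Respiratory chain genes were lower in 22 of 86 and 24 of 86 and higher in 6 and 3 (percentiles 0.01 and 0), although Cox8c was higher at 624 and 577 against 260.3. Histone genes were lower in 14 of 47 and 17 of 48 and higher in 3 in each, both at percentile 0, with Hist1h2ba at 348 and 408 FPKM against 888. Sertoli and Leydig cell genes lay below matched lists in both pellets, Sertoli with 5 of 19 and 9 of 19 lower and Leydig with 7 of 15 and 7 of 14 lower; of both lists, 1 Leydig gene in pellet1 was higher. Cyp17a1, a steroid-making enzyme, was at 51.0 and 66.2 FPKM against 139.5, and Ptgds, a prostaglandin synthase, at 6.29 in pellet2 against 46.4.

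Chromatoid body genes lay at percentile 6.53 in pellet1 (0 higher and 3 lower of 32) and 0.11 in pellet2 (1 and 1), with Ddx4 at 215 FPKM in both. The piRNA pathway lay at 4.29 and 0.27. Flagellum genes lay at 1.28 and 0.325 and proteasome genes at 0.6 and 0.03. Meiotic, spermatogonial and peritubular, vascular and blood genes lay at 0.695, 0.57 and 0.1 in pellet1 and at 13.4, 36.2 and 2.84 in pellet2, the last at 1.49 without genes listed at 0, and the difference between pellets was not tested. The meiotic list came to 4.28 at a mean of 5 FPKM and the spermatogonial list to 8.1 without the filter. Neat1 was at 147 FPKM in pellet1 and 242 in pellet2 against 76.7, whereas Malat1 was at 394 and 679 against 626. Speer4e, of a multicopy spermatid family, was at 718 FPKM in pellet2 against 105, with reads of its copies not told apart. MicroRNA genes lay at percentile 0 in both pellets, but at 99.8 and 98.5 when genes listed at 0 were left out.

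Of 12904 genes 2168 were higher and 1214 lower in pellet1, and of 12941 genes 1616 were higher and 933 lower in pellet2 (1955 and 1444, and 1399 and 1101, after centring). The authors' deposited table calls 216 higher and 10 lower in pellet1 and 96 and 3 in pellet2, of which 37 and 19 higher belong to the small nucleolar and nuclear RNA list. FPKM of genes shorter than the sequenced fragments is poorly defined, and reads of these RNAs and of their host genes cannot be told apart.

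**Figure D2:**
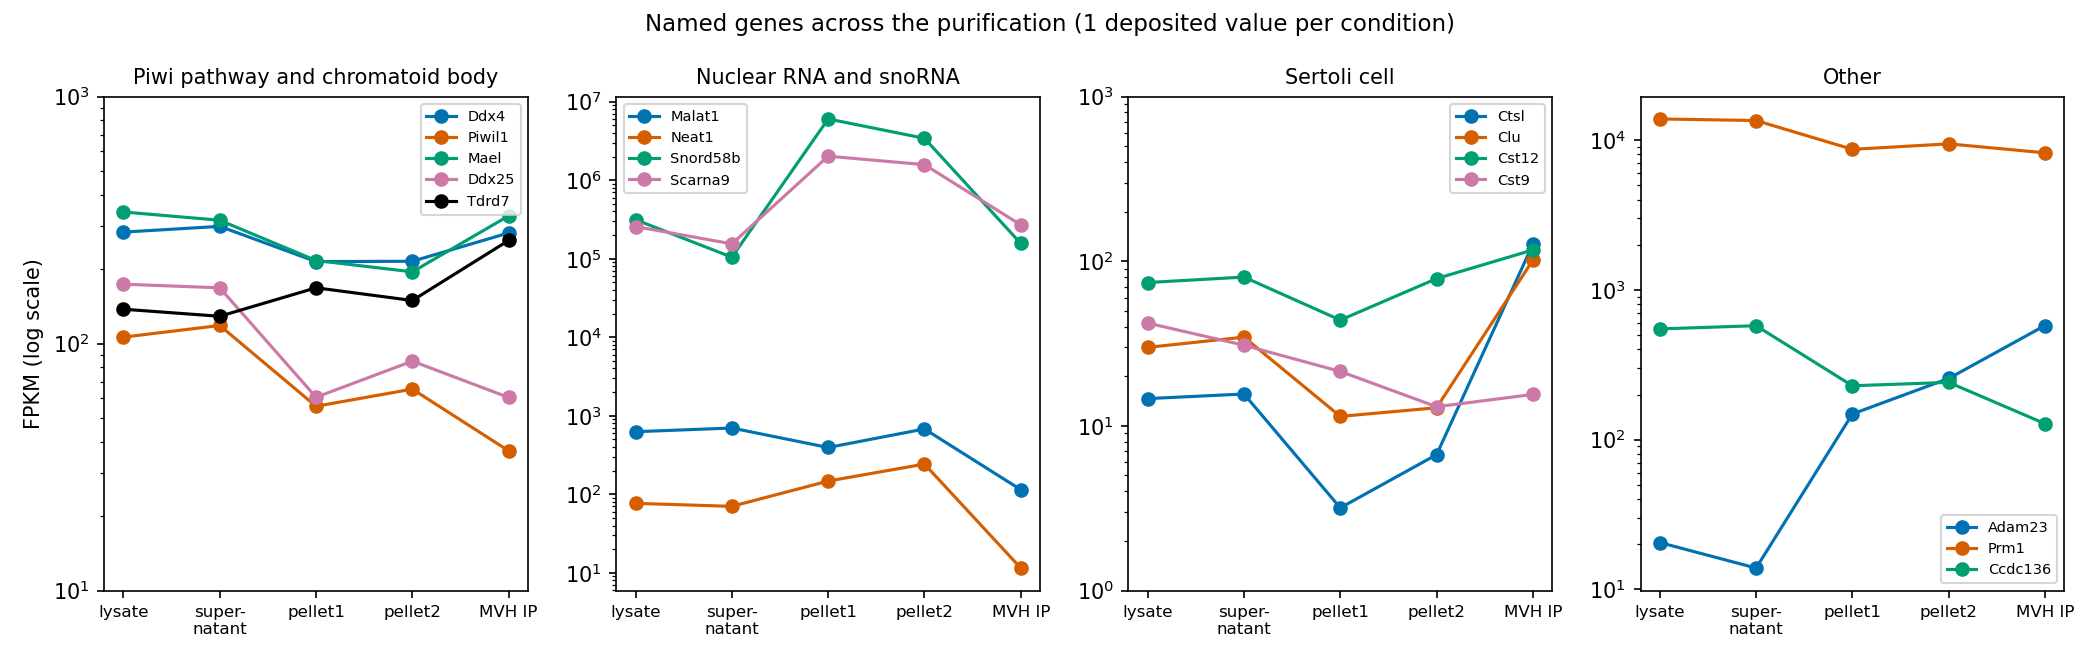
FPKM of named genes (log axes, a separate one per panel) across lysate, supernatant, pellet1, pellet2 and MVH IP, each point 1 deposited value and lines only joining them; the genes were chosen after their values were seen. Neat1 goes from 242 FPKM in pellet2 to 11.5 in MVH IP, and Ctsl from 6.68 to 127.

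MVH IP was set against pellet2, which per the protocol is the material that entered the IP. Most Sertoli cell genes at a mean of 1 FPKM or more were higher: 17 of 20 by 2-fold or more and 0 lower (14 and 1 centred), at percentile 100. The list has 26 members, of which the rest fell below that mean. Among these, Rhox8, Inha and Hopx were at 0 FPKM in MVH IP, against 3.03, 2.42 and 4.38 in lysate. Some of the 20 passed only through MVH IP, as Gata4 at 7.18 FPKM against 0.132 in pellet2 and Inhbb at 8.08 against 0.104. Ctsl was 16.6-fold higher (127 and 6.68 FPKM), Clu, a secreted chaperone, 7.38-fold (101 and 12.9), and Aard 38.6-fold (66.0 and 0.737). Etd, an X-linked gene (X:50788095-50796753), was at 218 and 1.52 FPKM, and Hist1h2aa, a testis histone, at 164 and 15.9. Nuclear RNAs went the other way, with Neat1 at 11.5 and 242 FPKM, a log2 ratio of -4.28, and Rmrp, the RNA of a ribonucleoprotein processing enzyme, at 576 and 8296.

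Of 103 small nucleolar and nuclear RNA genes 79 were lower and 5 higher (88 and 3 centred), at percentile 0, and of 8 nuclear-retained noncoding RNA genes 5 were lower and 0 higher, at 0.01. Host genes lay at 1.41. Respiratory chain genes (49 higher and 1 lower of 85, 21 and 4 centred), histones (35 and 5 of 56, 20 and 7 centred) and X and Y multicopy genes (7 and 2 of 11, 5 and 2 centred) lay above matched lists, the last at 99.3 but 96.9 with a pseudocount of 0.1 and 96.5 without genes listed at 0. Leydig genes, with 5 higher and 1 lower of 12, lay at percentile 51.6, and peritubular, vascular and blood genes had 10 higher and 4 lower of 22 and a median 0.01 from that of all genes, but lay at percentile 99.5 at a mean of 5 FPKM. At that filter spermatogonial genes lay at 99.8, against 20.7 at a mean of 1 FPKM. Chromatoid body genes lay at 0.16, with 1 higher and 0 lower of 32 (0 and 4 centred), as Ddx4 at 280.3 and 215 FPKM and Piwil1 at 36.8 and 65.4. Flagellum genes lay at 1.91, or 3.25 without the filter, piRNA pathway genes at 4.2 and ribosomal protein genes at 13.9.

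The median of all 13808 genes was 0.79, with 5513 higher and 798 lower, or 1958 and 1888 after centring. The authors' deposited table calls 88 higher and 14 lower, with q = 0.000904 for Ctsl, 0.0372 for Clu, 0.0113 for Aard and 1.66e-05 for Neat1 in the authors' deposited table. This comparison was chosen after seeing the data.

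MVH IP was next set against sorted round spermatids, the cells that carry the chromatoid body, in tables scaled apart from each other with a floor of 5 FPKM. The tables shared 3855 genes, while 4201 were listed for MVH IP alone and 1101 for round spermatids alone. Hist1h2ba, a testis histone, was at 532 FPKM in MVH IP and 12.6 in round spermatids, and Orc1, of the replication origin complex, at 631 and 5.49. Piwil1 was at 36.9 and 5.01 FPKM, Tdrd7, a Tudor protein of the chromatoid body, at 878 and 217, and Ddx4 at 249.9 and 119. Lower in MVH IP were Rps29 at 65.6 and 169.5 FPKM and Lin37 at 10.4 and 32.0. Braf was at 2243 and 13.6 FPKM and Ip6k1 at 5146 and 1508, but the joint table lists them at 29.2 and 93.0 in MVH IP, so these values depend on the table.

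The median log2 ratio was 1.85, so lists are best read relative to it. Flagellum genes had 20 higher and 0 lower of 32 (1 and 8 centred), at percentile 0.1, and ribosomal protein genes 25 and 2 of 55 (2 and 27 centred), at 0. Respiratory chain genes lay at 2.42, or 5.02 with a pseudocount of 0.1, and proteasome genes at 2.03. Chromatoid body genes had 11 higher and 0 lower of 16 (0 and 5 centred), at 3.77, and piRNA pathway genes 7 and 0 of 8 (1 and 1 centred), at 93.5. Of the Sertoli list 10 genes were listed for MVH IP alone, 1 for round spermatids alone and 0 for both, and histone genes numbered 40 against 4. In all 2905 genes were higher and 21 lower, or 781 and 829 after centring. The MVH IP values of the joint and the separate table were 4-fold or more apart for 899 of 7950 genes after their median shift, and 287 genes were lower with the joint table. One of the pooled round spermatid libraries was made from RNA above 500 bp, which bears on short transcripts such as those of histones and ribosomal proteins.

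Round spermatids were set against lysate to show which testis transcripts belong to these cells. Ccdc77 was at 879 FPKM in round spermatids and 7.20 in lysate, Ip6k1 at 1508 and 16.6, and Spata6, a sperm neck protein, at 1593 and 173. The joint table lists Ccdc77, Ip6k1 and Spata6 in lysate at 16.6, 40.7 and 394 FPKM, so the sizes of these differences depend on the table. Pabpc1, a poly(A)-binding protein, was at 1091 and 248 FPKM. Hist1h2ba was at 12.6 and 324 FPKM and Piwil1 at 5.01 and 52.2. The late packaging transcripts were lower, Prm1 at 1614 and 5046 FPKM and Tnp1 at 3459 and 7609, while Ddx4 was at 119 and 121. The joint table lists Ddx4 in lysate at 282 FPKM, so its near-equal level also depends on the table.

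Condensation genes, with 1 higher and 5 lower of 12 (1 and 6 centred), lay at percentile 0, retrogenes (1 and 3 of 27, 0 and 4 centred) at 0.07, ribosomal protein genes (6 and 18 of 62, 6 and 24 centred) at 0 and respiratory chain genes (9 and 4 of 66, 5 and 10 centred) at 0.03. Chromatoid body genes lay at 9.72 and piRNA pathway genes at 4.71. Sertoli and Leydig genes were listed for lysate alone in 6 cases each, and histone genes numbered 4 in round spermatids and 28 in lysate. Of 4105 shared genes 927 were higher and 148 lower with a median of 0.31, or 622 and 330 after centring. With the lysate values of the joint table they were 413 and 1790, so the direction of the balance depends on the table. The size selection of 1 round spermatid library cannot be told apart from the lower levels of short transcripts, among them Prm1, Tnp1, Hist1h2ba and ribosomal protein genes.

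Round spermatids of mice heterozygous for MIWI were compared with the other round spermatids. Piwil1, the targeted gene, was not lower, at 7.79 FPKM against 5.01. Ribosomal protein genes stood higher, Rps12 at 105 and 6.36 FPKM and Rpl17 at 110.1 and 7.02. Ip6k1 was at 22.1 and 1508 FPKM and Spata6 at 209 and 1593, and Prm2 at 380.4 and 1077; values of Ip6k1 and Spata6 depend on the table, since the separate tables list them at 5146 and 2988 FPKM in MVH IP and the joint one at 93.0 and 371. Of 36 ribosomal protein genes 27 were higher and 1 lower (22 and 1 centred) and of 30 respiratory chain genes 11 and 0 (5 and 0 centred), both at percentile 100. Chromatoid body genes lay at 64.4, with 1 higher and 0 lower of 9, and condensation genes at 11.7. Of 2536 shared genes 323 were higher and 267 lower, or 91 and 463 after subtracting the median of 0.43. The 1 heterozygous library comes from a separate table, and genotype, library and the size selection in the other round spermatids, which bears on short transcripts such as those of ribosomal proteins, cannot be told apart.

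Transposable elements of MVH IP and round spermatids were compared by class. LINE elements held 43.2% of the summed element FPKM in MVH IP and 50.2% in round spermatids, SINE 36.7% and 38.3%, LTR 17.3% and 10.3%, and DNA transposons 2.74% and 1.26%. Without the 10 highest elements SINE held 36.0% and 31.5%. Class medians, as a percent of the sum of the class medians, were 25.6% and 22.4% for SINE and 21.5% and 23.0% for LTR. That measure ignores how many elements a class has and is not a share of FPKM. The direction of SINE thus depends on the elements and the measure used. That of LTR stayed without the 10 highest elements and turned only with the class medians. LINE, SINE, LTR and DNA elements covered 10451275, 9050271, 14636855 and 919602 bp in MVH IP. In round spermatids they covered 3419306, 4002850, 4357032 and 462329 bp. The L1 fragment type HAL1-3A_ME alone held 30.2% of the sum in MVH IP over 1917 elements and 42.3% in round spermatids over 2469, with median lengths of 60 and 58 bp. At 12057 elements listed in both, the median log2 ratio was 2.43, and relative to it 0.59 for DNA, 0.12 for LTR, 0.21 for SINE and -0.42 for LINE. An internal MERVL part, MERVL_2A-int at 14:73185775-73190970, was at 9745 FPKM in MVH IP and 5.02 in round spermatids. FPKM of elements shorter than the fragments is poorly defined, and reads shared among copies cannot be told apart.

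**Figure D3:**
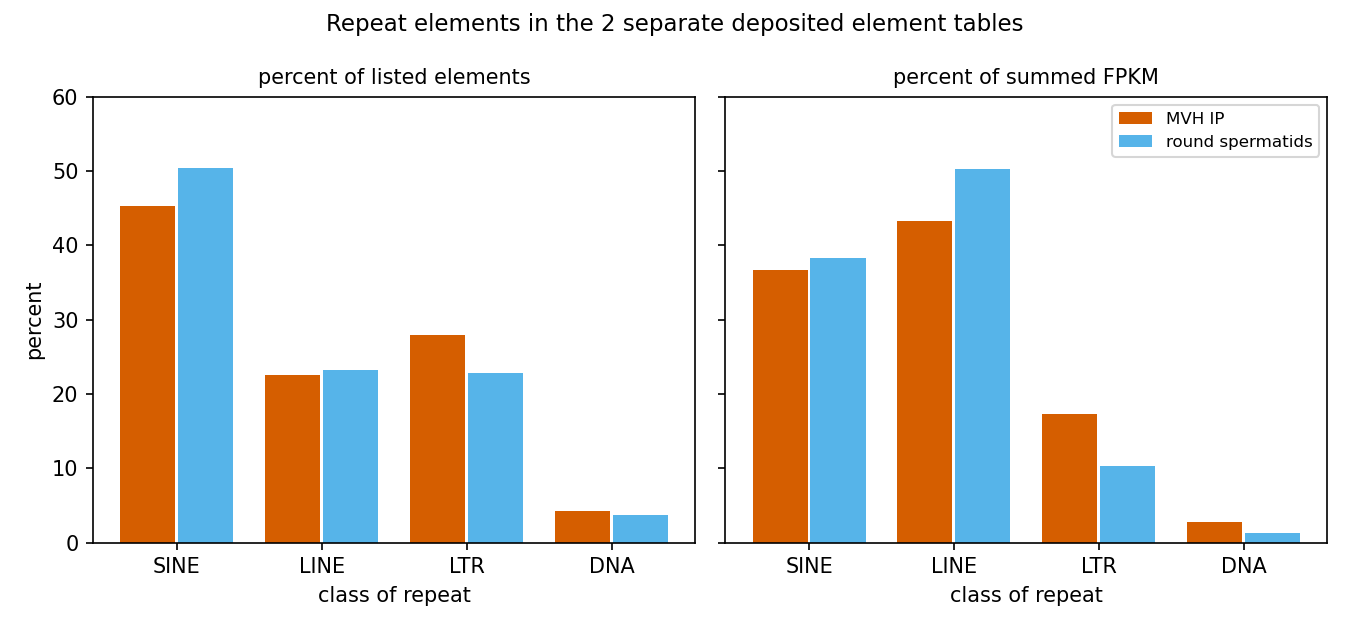
Percent of listed elements (left) and of the summed element FPKM (right) in each transposable element class, for MVH IP and round spermatids, scaled apart from each other. On the left, LTR elements are 28.0% and 22.8% of listed elements. LTR elements hold 17.3% and 10.3% of the summed FPKM. Their class medians, not drawn, are 21.5% and 23.0% of the sum of the class medians.

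piRNA clusters, the genomic sources of piRNA precursors, were compared in both kinds of table. Of 191 clusters in the joint table, 112 were higher and 3 lower in MVH IP than in lysate (19 and 10 centred), at percentile 86.3 of matched gene lists. Cluster 11 (2:150971252-150972811) was at 321 and 70.6 FPKM. Against lysate, clusters lay at percentile 0 in pellet1, 99.9 in pellet2 and 32.7 in supernatant. The shifts in the pellets were small, at -0.27 and 0.20 relative to all genes. In pellet1 4 clusters were higher and 8 lower of 189, and in pellet2 13 and 7 of 191. In MVH IP against pellet2 64 were higher and 5 lower of 191 (13 and 16 centred), at percentile 67.2. The separate tables listed 174 clusters for MVH IP and 70 for round spermatids, and all 52 listed in both were at least 2-fold higher in MVH IP, with medians of 35.4 and 1.21 FPKM. Their median log2 ratio was 4.27. The MVH IP table starts at 5.89 FPKM while the round spermatid table starts at 0, so clusters low in MVH IP could not enter, and the ratio cannot be set against that of genes listed from 5 FPKM in both tables. Cluster 119 (10:86038120-86039479) was at 99.1 and 0.562 FPKM.

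Other noncoding RNAs differed by class between MVH IP and round spermatids. Of 99 shared lincRNA genes 85 were higher and 0 lower in MVH IP, with a median log2 ratio of 2.74. Of 123 microRNA genes 79 were higher and 22 lower, of 146 snoRNA genes 79 and 10, of 234 snRNA genes 49 and 85, and of 34 rRNA genes 7 and 9. The medians of these 4 classes were 1.73, 1.15, -0.29 and -0.20, against 0.84 over all these RNAs and 1.85 for genes of the gene tables. As those tables are scaled apart, whether microRNA and snoRNA genes moved relative to genes could not be told. The round spermatid values pool a library made from RNA above 500 bp. Its size selection cannot be told apart from the levels and shares of these 4 short classes. The lincRNA Gm13166 (ENSMUSG00000085525) was at 1176 and 77.0 FPKM, and the snRNA gene ENSMUSG00000064447 at 223 and 10221. Over all tables of each sample, elements held 87.7% of the summed FPKM in MVH IP and 72.2% in round spermatids, snoRNA 7.63% and 12.2%, snRNA 0.891% and 10.2%, and genes 2.82% and 3.83%. The medians of snRNA lay closer, at 142 FPKM in MVH IP and 189 in round spermatids. Each class median was also taken as a percent of the sum of the class medians, which ignores how many features a class has. By this unlike measure snoRNA stood at 14.8% and 5.31%, and genes at 4.95% and 4.25%, both in the other direction. Elements stood at 2.89% and 2.85%, which is not a share of the summed FPKM. These sums join tables scaled apart, and FPKM gives short RNAs a large weight.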

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

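All tests in this part were chosen after the results were seen. Small nucleolar and nuclear RNA genes had a median log2 ratio against lysate of -1.15 in supernatant, 2.86 in pellet1 and 1.89 in pellet2, opposite directions whose difference was not tested. Assembled transcripts with no gene name, which the report's counts leave out and only the counts over all features include, were at least 2-fold higher in MVH IP than in lysate in 2495 cases and lower in 1233. In the lysate element table, set against no other, rRNA repeats held 58.2% of the sum.

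For the small nucleolar and nuclear RNA genes, higher in the pellets and lower in MVH IP, nuclear RNA of every kind stays open: 0 of 9 nuclear-retained noncoding RNA genes were 2-fold higher in pellet1 and 1 of 10 in pellet2, Neat1, but 4 of the 9 were at 5 FPKM or more in lysate. A bias of short genes stays open in MVH IP, where 10 other genes of at most 200 nt above 0 in both had a median of 1.53, against -0.28 for the list so restricted, but 53 such genes with zeros kept had -4.33, against -1.01. It stays open in the pellets too, with a median of 1.40 and a lower quartile of -1.44 over 15 genes, and -4.26 over 46 with zeros kept; the forms with zeros were the first ones and were replaced after their values were seen. Host transcripts stay open too, with values that go both ways. Their median in pellet1 was 0.70 (4 higher and 1 lower of 10). In MVH IP against lysate it was 1.13 (5 higher and 1 lower of 10), while the small RNA list was at -1.01. In MVH IP against pellet2 the host median was 0.18 (3 higher and 2 lower of 10), while the small RNA list was at -2.87. Relative to all genes, host genes and list were at -0.61 and -3.67 against pellet2, and at 0.22 and -1.92 against lysate. The direction of the host genes against pellet2 thus depends on centring. No biological explanation was tested.

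For the higher median gene in MVH IP than in lysate, a flat background large enough to give the whole gain is argued against. Only 2.67% of 1122 olfactory receptor genes reached the gain of 8.78 FPKM. Their mean was nevertheless 0.765 FPKM in MVH IP and 0.363 in lysate, although 19.3% and 35.5% of them were above 0. A smaller background, or a factor shared with these genes, is not excluded by this. Few sampled molecules in low genes are argued against by a median of 0.92 over 4993 genes at 20 FPKM or more. One factor for the whole library is argued against only by 29 genes above 1000 FPKM, whose median was -0.02 and which made the bin medians span 1.09. A first form of that test over 1 to 1000 FPKM gave 0.32, within its bound, and was replaced after that value was seen, so a factor shared by genes below 1000 FPKM stays open. Lysate itself differed between the separate and the joint table by a median log2 of -1.21 over 5254 genes, with a rank correlation of 0.93. A shift larger than the 0.92 of MVH IP thus occurred with no change of sample. No biological explanation was tested.

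For the Sertoli cell genes, higher in MVH IP than in pellet2, more material of every somatic type stays open: the higher of the Leydig and the peritubular, vascular and blood percentiles was 51.6, but members of both lists went both ways, with upper quartiles of 0.34 and 1.24 relative to all genes against a Sertoli lower quartile of 0.83, and the peritubular list reached 99.5 at a mean of 5 FPKM. Genes at exactly 0 in pellet2 are argued against, since 19 of the 20 genes were above 0 in both, with a median of 1.59 relative to all genes. Leaving out so few could hardly move the median. Values just above 0 in pellet2, as Gata4 at 0.132 FPKM, were not addressed. The Sertoli list was itself low in pellet2 against lysate, at -0.99 relative to all genes (0 higher and 9 lower of 19). In MVH IP against lysate it was at 0.78. Low pellet2 values are thus part of the difference between MVH IP and pellet2. More Sertoli cell material in MVH IP could not be told apart, since its test used MVH IP against lysate and not against pellet2. In it 5 of 9 Sertoli genes at 5 FPKM or more in lysate lay above the median gene. Ctsl was at 127 FPKM in MVH IP and 14.6 in lysate, but Cst9 at 15.5 and 42.1. In pellet2 Cst9 was at 13.1 FPKM, so it was not lower in MVH IP than there. Sertoli cells are not among the groups of the design, so no biological explanation was tested.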

How the results depend on the processing

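Settings added after seeing the data were all features, genes above 0 in both conditions, other references and the other table of the same group. No paired analysis was possible because the deposited values pool the libraries of a group. Leaving out each replicate, a replicate block, count-based normalisations, leaving out the size-selected round spermatid library and adjusted p without a fold threshold for the round spermatid comparisons were not run, for lack of values per library, counts or q-values. In tables with a floor of 5 FPKM the filters removed nothing. Centring shifts every gene alike and cannot move a percentile, so its percentiles, and those of the filters in such tables, stayed by construction. With these included, 270 percentiles of single lists stayed on their side, 10 came within the central 95% and 2 reversed. A further 3 had too few members at a mean of 5 and gave no value. In 7 cases a list within the central 95% came outside it. At a mean of 5 these were spermatogonial (99.8) and peritubular, vascular and blood genes (99.5) in MVH IP against pellet2 and host genes in supernatant (0.02). Without a filter they were X and Y genes in pellet1 (97.7) and retrogenes in pellet2 (2.21), and above 0 in both, peritubular genes in pellet2 (1.49) and microRNA genes in supernatant (1.77). Of the counts and shares 106 stayed and 70 moved, where a count that changed by no more than a set ratio was taken to stay. The 2 that reversed were microRNA genes above 0 in both conditions, at percentile 99.8 in pellet1 and 98.5 in pellet2, where dropping zeros is the cause by construction. For the rest the cause was not tested, except that centring, a 4-fold threshold, stricter filters and more features move counts by construction.

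For MVH IP against lysate, 6554 higher became 2587 centred, 2337 at 4-fold, 735 by the authors' deposited table and 3002 in the separate gene tables. The 1043 lower became 451 at a mean of 5, 2852 centred, 352 at 4-fold, 2279 over all features, 639 above 0 in both, 12 by the authors' deposited table and 18 in the separate gene tables. In supernatant 96 higher became 241 with a pseudocount of 0.1, 40 at a mean of 5, 615 over all features and 62 above 0 in both, and 186 lower became 358, 108 and 454 with the first 3 of these. In pellet1 2168 higher became 3288 over all features, and 1214 lower became 705 at a mean of 5 and 2448 over all features. In pellet2 1616 higher became 1055 at a mean of 5 and 2930 over all features, and 933 lower became 441 and 1659. For MVH IP against round spermatids 2905 higher became 781 centred and 1759 at 4-fold, and 21 lower became 829, 0 and, with the joint table, 287. For round spermatids against lysate 927 higher became 247 at 4-fold and 413 with the joint table, and 148 lower became 330 centred, 17 at 4-fold and 1790 with the joint table. For heterozygous MIWI 323 higher became 91 centred and 267 lower became 463.

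Shares by medians per class are each class median as a percent of the sum of the class medians, not of the summed FPKM. Without the 10 highest features, and then by medians per class, MVH IP shares were 2.99% and 27.5% for DNA, 45.4% and 25.4% for LINE, 15.6% and 21.5% for LTR and 36.0% and 25.6% for SINE. In round spermatids they were 1.43% and 23.1%, 57.1% and 31.5%, 10.03% and 23.0%, and 31.5% and 22.4%. Over all tables MVH IP shares were 3.10% and 4.95% for genes, 5.21% and 14.8% for snoRNA and 89.7% and 2.89% for elements. In round spermatids they were 4.31% and 4.25% for genes, 10.5% and 44.8% for snRNA, 8.67% and 5.31% for snoRNA and 74.7% and 2.85% for elements. The median log2 ratio of shared piRNA clusters, 4.27, was 4.21 without the 10 highest, 4.44 at values of at least 1 and 4.04 as a ratio of medians.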

Other observations

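No test was run for this part. Single genes of other cell types moved apart in MVH IP relative to lysate. C1qb, a complement gene of macrophages, was at 43.4 FPKM in MVH IP and 6.73 in lysate, and Uchl1, a marker of spermatogonia, at 28.0 and 5.48. Hba-a1, a globin gene of red blood cells, was at 8.91 and 45.2 FPKM, and Actg2, a smooth muscle actin gene, at 205 and 214. Insl3, a hormone of Leydig cells, was at 39.6 and 78.1 FPKM, whereas Scarb1, a lipoprotein receptor, was at 60.1 and 21.5. Sorted round spermatids also held Actg2 and Scarb1, at 93.4 and 10.3 FPKM, against 89.1 and 9.06 in lysate in the separate gene tables. These 2 genes were thus not particular to other cell types here.

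piRNA cluster 177 (17:39983505-39984882), at 61170.5 FPKM in MVH IP and 75327 in lysate, lies within a repeat annotated as small subunit rRNA (17:39983298-39985146) in the lysate element table. Mir715 (17:39981081-39981190), on the same chromosome near that repeat, was at 19308 FPKM in pellet1 and 1558 in lysate.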
